A study of Mus musculus with 7 samples.

How the data were processed

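The series holds RNA-seq of 7 mouse motor cortex samples, 3 labelled WT and 4 labelled cKO, each a separate library; the titles number the replicates 1 to 3 in WT and 1 to 4 in cKO. Per the labels' protocols, complementary DNA was made from fragmented mRNA with random primers, and the second strand was made with ordinary nucleotides, so the protocol describes no strand marking. The labels do not say that each library is from a separate mouse in so many words; p-values measure the spread between these libraries. The deposited tables hold the authors' raw gene counts and the authors' FPKM values for the same 54532 genes, with gene symbol, position and biotype in the same rows. Per the submitters' processing notes, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the mm10 build. The aligner, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of genes that overlap, lie antisense to one another or have near-identical copies are therefore uncertain. The FPKM values deposited by the authors imply a library total between 0.968 and 1.02 times the sum of the gene counts, so they were not scaled by that sum. There were 0 rows without a gene name.

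Library totals were sums of the deposited counts and lay between 15181390 and 16463721, so depth was alike in all libraries, and genes with at least 1 count numbered between 23168 (cKO replicate 3) and 24956 (WT replicate 2). Mitochondrially encoded genes held 5.50% to 6.40% of counts in WT and 5.68% to 7.54% in cKO, the highest in cKO replicate 3. Chi-square statistics per degree of freedom between pairs of libraries ran from 4.76 to 25.5, so no pair agreed within sampling noise and each library counted as 1 replicate.

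The comparison of cKO with WT used edgeR 4.0.16 in R 4.3.3 on the raw counts, with TMM factors, the default filterByExpr filter, which left 16308 genes, and the quasi-likelihood F test with genotype as the factor. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Standard errors are the log2 fold change divided by the root of the F statistic, and intervals are 95% intervals. CPM were taken from edgeR with the TMM-scaled library sizes. Single values were also compared with exact two-sided permutation tests (SciPy 1.17.1). Figures were drawn with matplotlib 3.10.9.

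Before the data were examined, 35 gene lists were written for chaperones, stress responses, disease genes, cell types and neighbouring tissues, along with the test designs, the other settings to try and the rule for named genes. Of these lists, 34 were tested, each with at least 5 measured members; the list of sex-linked genes was used only to tell the sexes apart. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 34 lists. Beside it stand camera with a correlation estimated per list, and fry, whose p tests whether a list's genes move on balance in one direction. Lists share genes: Hspa5 and Hyou1 are in both the HSP70 and the unfolded protein response lists, and Hsp90b1 is in the latter and in the list of other heat shock genes. The mean of a list in a library is the mean over its genes of log2 CPM minus the gene's mean over the 7 libraries.

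The rule named Tia1 and, with no gene past the threshold, the 5 genes with the smallest p in each direction, then every measured HSP70 member, and for each other list its past-threshold members or else the 2 with the highest mean CPM. Those examples are printed for the lists that passed camera with the preset correlation and for stress granule components. Genes named because they passed adjusted over a list alone, and genes named for single libraries, were chosen after their values were seen. A result for 1 gene that the rule covers is not reported here.

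The replicate numbers are shared by both groups, and no label says what a number stands for. Deviations from the group means correlated at 0.110, 0.128 and 0.122 across genes for the pairs numbered 1, 2 and 3, each above 0.1, and by that rule the numbers were taken to pair the libraries. Pairs with different numbers correlated higher, WT replicate 2 with cKO replicate 4 at 0.210 and WT replicate 1 with cKO replicate 3 at 0.129, so the support for this pairing is weak. The fit with the number as a block is an alternative, printed where it changes a call; number 4 has no WT partner, so cKO replicate 4 adds nothing to its fold changes.

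Other alternatives were other scalings (RLE, upper quartile, library size only), no filter and a stricter filter on low counts (CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, and with no filter. Y-linked expression as a covariate, protein-coding genes alone, an adjusted p under 0.1, a fold change of at least 1.5 and leaving out each library in turn were also run. After the data were seen, fits without cKO replicates 3 and 4, lists without shared genes, and the HSP70 list without Hspa1a and Hspa1b were added. The edgeR fit was repeated on all 35 splits of the 7 libraries into 3 and 4.

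The tests were checked on simulated counts with 200 of 16308 genes changed. The edgeR test called 32%, 72%, 92% and 100% of genes changed by factors of 1.41, 2, 2.83 and 8 (50 genes each) and 19 of 16108 unchanged genes. The true calls were 16, 36, 46 and 50 genes, so false calls made up a larger share than the 0.05 aimed at. In a simulation with 1 list shifted by 0.3 on the log2 scale, camera called that list and 0 of the 33 other lists. Each gene was drawn independently in both simulations. In the real lists the estimated correlation between genes ran from -0.03 (p53 and apoptosis genes) to 0.93 (blood cell markers). The simulation therefore cannot show how often camera calls unshifted lists whose genes vary together.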

Results

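RNA was sequenced from 7 motor cortex samples of mice that had all been injected on postnatal day 0, into both lateral ventricles, with a virus named GA100. The series title places the mice in a model of C9orf72 poly-GA disease, in which a dipeptide repeat protein of glycine and alanine is produced, and sampling followed 3 months after injection. The labels give 3 wild-type (WT) and 4 conditional knockout (cKO) samples, and no uninjected animals were analysed here, so every comparison is between genotypes under the same virus. Total gene counts per library ran from 15213977 to 16463721 in WT and from 15181390 to 16403202 in cKO. Of 54532 annotated genes, 16308 passed the filter on low counts and were tested. WT replicate 1 and cKO replicate 1 carried Xist transcripts (15217 and 19151 counts) and 0 counts of the Y-linked gene Ddx3y, and the other 5 libraries had between 1073 and 1386 counts of Ddx3y.

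The title names TIA1, an RNA-binding protein that nucleates stress granules, and Tia1 was therefore read as the gene targeted in the cKO mice. Tia1 (ENSMUSG00000071337, chromosome 6, 86404219 to 86433405, mm10, a protein-coding gene on the forward strand) was not lower in the libraries labelled cKO. Its level was 75.1 ± 18.4 CPM (SD, n = 3) in WT and 79.1 ± 4.29 CPM (SD, n = 4) in the libraries labelled cKO. The log2 fold change, cKO minus WT here and throughout, was 0.07 ± 0.13 (SE), with a 95% interval from -0.21 to 0.36 and an edgeR quasi-likelihood adjusted p of 0.914. An exact two-sided permutation test of log2 CPM over the 35 splits of the libraries gave p = 0.571, where the smallest p this design allows is 0.0571. The WT libraries spread widely, with 60.6, 95.8 and 68.9 CPM in replicates 1 to 3, and leaving out WT replicate 1 turned the sign of the fold change (-0.06). Without WT replicate 2 it was 0.28, with a 95% interval from 0.07 to 0.49 and an edgeR adjusted p of 0.491. The labels do not name the deleted exons or the cells that carry the deletion, so a count over the whole gene cannot show whether a part of the transcript was lost, and the labels were not checked by this gene. Directions below are for the libraries labelled cKO.

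The first question was which transcripts differed between motor cortex of WT and cKO mice. Among the genes with the smallest p, the inducible HSP70 gene Hspa1b stood at 9.46 ± 2.06 CPM (SD, n = 3) in WT and 28.5 ± 9.82 CPM (SD, n = 4) in cKO, a log2 fold change of 1.59 ± 0.26 (SE). Slc5a3, a myo-inositol transporter, had 43.2 ± 1.22 CPM in WT and 75.9 ± 20.4 CPM in cKO, and Qk, the RNA-binding protein quaking, had 420 ± 24.8 and 554 ± 23.0 CPM. Dio2, an iodothyronine deiodinase, and Fgfr2, a fibroblast growth factor receptor, completed the 5 genes with the smallest p among those with higher values, at log2 fold changes of 0.42 and 0.46. On the other side stood Ccbe1 (-0.78), Galnt16 (-0.34), the receptor phosphatase Ptpru (-0.48), Islr2 (-0.36) and Glt8d2 (-0.48). Over the alternatives that do not leave out just 1 library, log2 fold changes ran from -0.84 to -0.38 for Ccbe1 and from 0.53 to 0.81 for Slc5a3. The 7 values of each of these 10 genes did not overlap between groups.

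None of these genes passed the threshold in the edgeR quasi-likelihood test, which called 0 of 16308 genes at an adjusted p under 0.05; all 10 had an adjusted p of 0.669, the smallest found. At an unadjusted p under 0.05 the test listed 1164 genes, 7.14% of those tested. DESeq2 called 3 genes, all with higher values in cKO, namely Hspa1b, Qk and Slc5a3, with adjusted p of 7.26e-07, 0.00244 and 0.00872. Limma-voom called 0 genes, with 1106 at an unadjusted p under 0.05. With the replicate number as a block, edgeR called 2 genes, Cadm2 with a higher and Rpl30 with a lower value in cKO. That fit takes its fold changes from replicates 1 to 3, as number 4 has no WT partner, and cKO replicate 4 lay within the WT range for both: 235 CPM of Cadm2 (222 to 271 in WT) and 64.1 CPM of Rpl30 (33.5 to 65.5 in WT). Groups did not overlap for 1204 genes (7.38%), where chance gives 5.71% on average. Genes vary together, so neither share shows an excess over chance. Some other splits of the 7 libraries listed more than 1164 genes at an unadjusted p under 0.05 in edgeR, up to 2501. Most other splits listed fewer. On counts simulated from these libraries the edgeR test called 32% of genes changed by a factor of 1.41, 72% of those changed by a factor of 2 and 92% of those changed by a factor of 2.83, with 50 genes at each size. Genes were drawn independently in that simulation, and many were changed at once, some by a factor of 8. Its shares therefore cannot show how often real changes of these sizes would be called in these libraries.

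**Figure D1:**
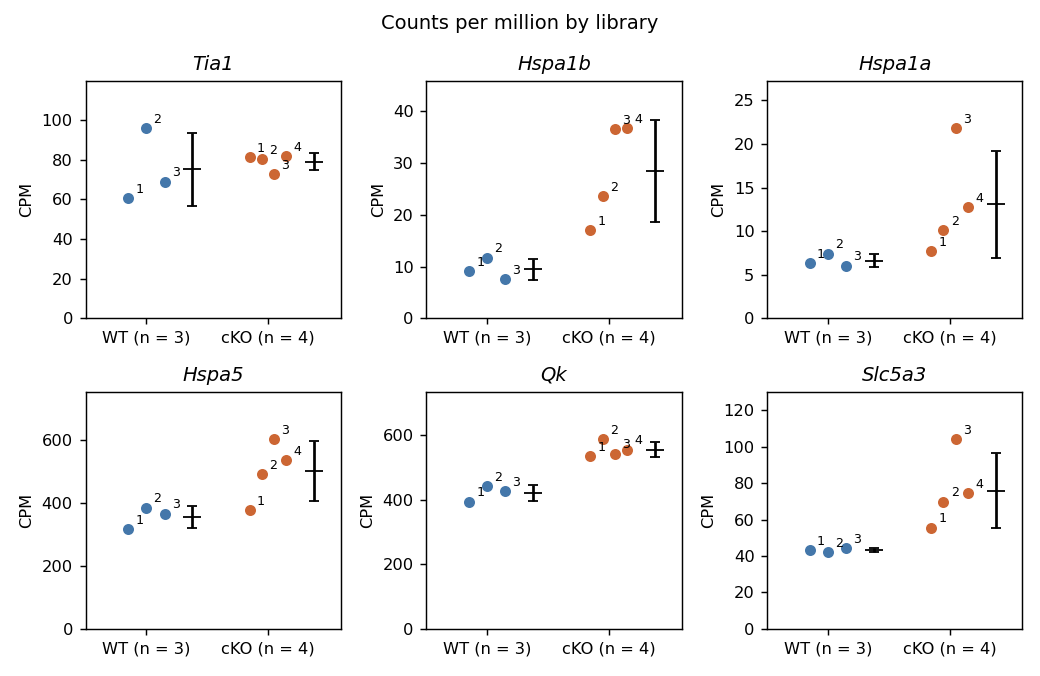
CPM (y axes, linear, starting at 0) of Tia1, 3 HSP70 family genes, Qk and Slc5a3 in each library, with the replicate number beside each point and the mean ± SD drawn in black. Tia1 lies between 60.6 and 95.8 CPM in WT and between 72.7 and 81.9 CPM in cKO, while each cKO library lies above each WT library for Hspa1b, Hspa1a, Qk and Slc5a3.

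The title puts transcripts of the HSP70 family, chaperones that bind unfolded proteins, at the centre of the study. Of 15 measured members, 12 had a positive and 3 a negative log2 fold change, with a median of 0.10. The inducible genes led: Hspa1b as above, and Hspa1a with 6.57 ± 0.739 CPM (SD, n = 3) in WT and 13.1 ± 6.15 CPM (SD, n = 4) in cKO, a log2 fold change of 0.99 ± 0.29 (SE). Hspa5, the endoplasmic reticulum chaperone BiP, had 356 ± 35.3 CPM in WT and 502 ± 94.6 CPM in cKO, a log2 fold change of 0.50 ± 0.14 (SE). Its groups overlapped, with 378 CPM in cKO replicate 1 and 386 CPM in WT replicate 2, and the exact two-sided permutation p was 0.114. Values for Hspa4l and Hsph1 were 0.29 and 0.32, and those of Hyou1, Hspa14, Hspa4, Hspa13, Hspa8, Hspa12a and Hspa9 ran from 0.04 to 0.14. Hspa8, the constitutive member and the most abundant, had 1365 ± 123 CPM in WT and 1439 ± 277 CPM in cKO. Hspa1l, Hspa2 and Hspa12b had 0.00, -0.04 and -0.13. No member changed sign under the other scalings, but without cKO replicate 3 the values of Hspa13, Hspa8, Hspa12a and Hspa9 fell below 0, between -0.05 and -0.01, and Hspa1a had 0.62. Leaving out 1 library also moved Hspa4 to between 0.014 and 0.17, Hspa14 to between 0.042 and 0.14, Hyou1 to between 0.096 and 0.21 and Hspa12b to between -0.23 and -0.05.

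Adjusted over all genes tested, 0 of the 15 members passed the edgeR threshold, with 5 at an unadjusted p under 0.05; DESeq2 called Hspa1b and limma-voom called none. Adjusted over the list alone, 3 were higher in cKO (Hspa1b, Hspa5 and Hspa1a); the study's title names this family from these samples, so this count is not independent evidence. That count was 5 with the replicate block, 1 (Hspa1b) without any single WT replicate, 6 without cKO replicate 1, 2 with limma-voom and 1 on the FPKM values. Without cKO replicates 3 and 4 it was 1 (Hspa1b), and Hspa1a and Hspa5 had log2 fold changes of 0.43 and 0.28. As a list, the family ranked above other genes in camera with a preset correlation of 0.01 (adjusted p = 0.00705), and this call was lost with an estimated correlation (adjusted p = 0.749) and without cKO replicate 3 (adjusted p = 0.0524). Without Hspa1a and Hspa1b the adjusted p was 0.0772, an alternative added after the data were seen. Hspa1b (chromosome 17, 34956436 to 34959238) and Hspa1a (chromosome 17, 34969190 to 34972156) are near-identical copies. How reads that match both were counted is not given. Their sum does not depend on how such reads were split between them, but it lacks any that were left out of both. It was 16.04 ± 2.79 CPM (SD, n = 3) in WT and 41.6 ± 15.2 CPM (SD, n = 4) in cKO, 2.59 times as high. Each cKO library (24.7 to 58.4 CPM) lay above each WT library (13.6 to 19.1 CPM), and the exact two-sided permutation p was 0.0571, the smallest this design allows. Any groups that do not overlap reach that p, as those of 1204 tested genes do, so it adds nothing to these ranges.

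Genes of the endoplasmic reticulum unfolded protein response all had positive log2 fold changes, 19 of 19, with a median of 0.21. Adjusted over the list alone, 7 were higher in cKO: Sdf2l1 (0.58 ± 0.16, SE), Pdia4 (0.54 ± 0.16), Hspa5, Xbp1 (0.38 ± 0.12), Dnajc3 (0.38 ± 0.12), Herpud1 (0.38 ± 0.10) and Manf (0.32 ± 0.11); with the replicate block the call for Manf was lost. Xbp1 encodes a transcription factor of this response, and the others assist folding, disulfide formation or disposal of proteins in that compartment. Canx, a lectin chaperone of the same compartment, had 0.12 ± 0.10, and 0.036 without cKO replicate 3. Values of the 7 genes were smaller in some settings: without cKO replicates 3 and 4 Hspa5 had 0.28. Over the settings that do not leave out just 1 library, the lowest were 0.37 for Sdf2l1, 0.27 for Pdia4 and 0.23 for Xbp1. They were 0.20 for Dnajc3, 0.22 for Herpud1 and 0.16 for Manf. Over all genes 0 of the 19 passed in edgeR, with 8 at an unadjusted p under 0.05, and 0 in limma-voom or DESeq2. The list passed camera with the preset correlation (adjusted p = 6.28e-08) and lost the call with an estimated correlation (p = 0.0741, adjusted p = 0.749). Its mean was highest in cKO replicates 3 and 4 (0.22 and 0.21 above the mean of all libraries), while cKO replicate 1 (-0.075) lay next to the highest WT library (replicate 2, -0.078).

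Other heat shock and co-chaperone genes had 22 positive and 6 negative values among 28 measured, with a median of 0.17. The most abundant members, Hsp90ab1 and Hsp90aa1, had 0.12 ± 0.09 (SE) and 0.25 ± 0.15, and 0.077 and 0.084 without cKO replicate 3; Hsp90ab1 had 0.06 without WT replicate 2. Adjusted over the list alone 0 passed in edgeR, with 6 at an unadjusted p under 0.05. Camera gave an adjusted p of 0.000152 with the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.749) and without cKO replicates 3 and 4 (adjusted p = 0.0771). Stress granule components did not pass as a list (adjusted p = 0.0772), with 18 of 30 values above 0. Hnrnpa2b1 and Ddx3x, its most abundant members, had 0.15 ± 0.07 and -0.02 ± 0.12. Fxr1, an RNA-binding protein related to the fragile X protein, was higher in cKO adjusted over the list alone (0.38 ± 0.09; 56.8 ± 2.72 CPM in WT, n = 3, and 73.9 ± 6.87 CPM in cKO, n = 4), a call lost with the replicate block. Targets of the integrated stress response showed no shift to one side, with 10 positive and 10 negative values and an adjusted p of 0.895.

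**Figure D2:**
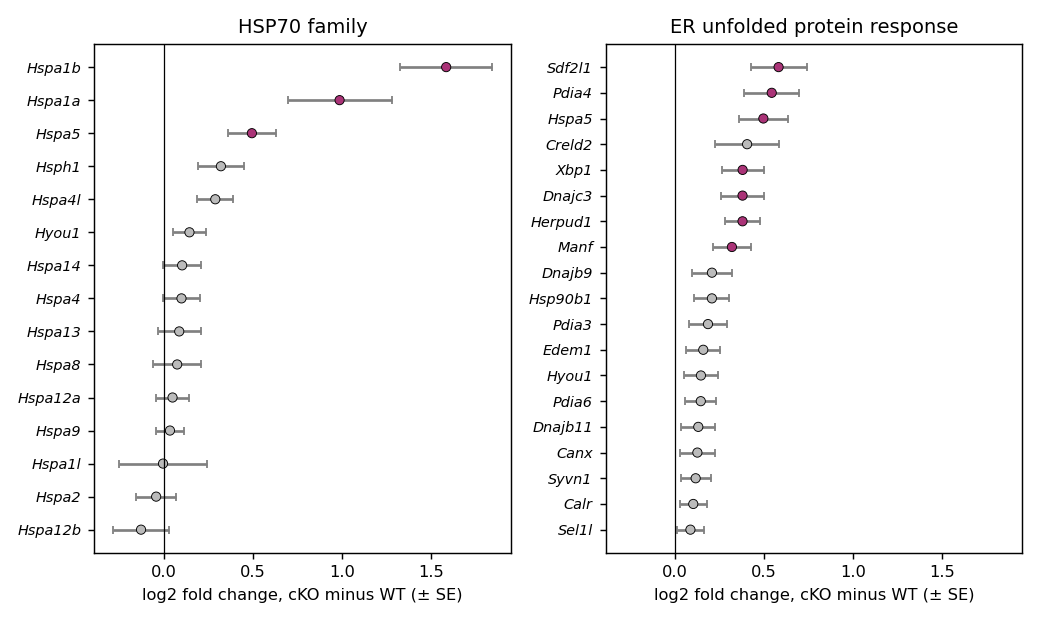
Log2 fold change, cKO minus WT, ± SE from the edgeR fit (x axes) for each measured member of the HSP70 family (left, 15 genes) and of the endoplasmic reticulum unfolded protein response (right, 19 genes); purple points have an adjusted p under 0.05 over the list alone, grey points do not. Hspa1b (1.59) and Hspa1a (0.99) lie apart from the rest of the family, and each of the 19 genes at right lies above 0.

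Among cell type markers, those of myelin and oligodendrocytes had 15 positive values of 15, with a median of 0.35, and those of excitatory neurons had 12 negative values of 15, with a median of -0.21. Adjusted over the list alone, the myelin genes Ugt8a (0.69 ± 0.17, SE), Ermn (0.68 ± 0.22) and Aspa (0.42 ± 0.14) were higher in cKO, while Mbp had 0.33 ± 0.21, and 0.20, 0.21 and 0.52 without WT replicate 1, cKO replicate 2 and cKO replicate 3. With the replicate block Ugt8a kept this call and Ermn and Aspa lost it. Slc17a7, the vesicular glutamate transporter of cortical neurons, had 1305 ± 184 CPM (SD, n = 3) in WT and 1058 ± 59.2 CPM (SD, n = 4) in cKO, and Camk2a had 3132 ± 297 and 2705 ± 370 CPM. Camera with the preset correlation gave adjusted p of 0.000182 for myelin and 0.0013 for excitatory neurons. With an estimated correlation the p were 0.266 and 0.0536, and the adjusted p were 0.749 for both. The myelin mean followed single libraries more than the groups: it was lowest in WT replicate 1 (-0.61) and cKO replicate 3 (-0.44), and these were the libraries with the highest meningeal fibroblast means (0.68 and 0.84).

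Markers of striatal medium spiny neurons, cells of a region beneath the cortex, had 14 positive values of 14, with 0.29 ± 0.17 (SE) for Pde10a and 0.15 ± 0.14 for Adcy5. Without cKO replicate 2 these fell to 0.11 and 0.0062; Pde10a had 0.17 without WT replicate 1 and Adcy5 0.25 without cKO replicate 1. Their means were highest in cKO replicates 2 and 3 (0.59 and 0.29) and ran from -0.39 to 0.03 in the other 5 libraries. The list passed with the preset correlation (adjusted p = 0.00511), not with an estimated one (adjusted p = 0.749). The call was also lost without WT replicate 1 (0.0903), cKO replicate 2 (0.16) or cKO replicate 3 (0.0524), each an adjusted p. Immediate early genes, transcribed within minutes of neuronal activity, had 19 positive values of 23, with 0.36 ± 0.11 for Homer1 and 0.26 ± 0.10 for Egr1. Their adjusted p was 0.00901 with the preset correlation, 0.749 with an estimated one and 0.0918 with the replicate block. It was 0.448 without WT replicate 2, the library with the lowest mean (-0.27), 0.0549 without cKO replicate 4 and 0.101 without cKO replicates 3 and 4.

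Lower values in cKO, by small amounts, were found for nuclear-encoded oxidative phosphorylation genes (59 of 74 negative, median -0.07), cytosolic ribosomal protein genes (52 of 76 negative, median -0.05) and proteasome subunits (29 of 37 negative, median -0.06). Atp5b and Atp5a1, subunits of ATP synthase, had -0.02 ± 0.08 (SE) and -0.03 ± 0.08. Rpl3 and Rpl4 had -0.05 ± 0.07 and -0.04 ± 0.07, and Psmd2 and Psmd1 had -0.12 ± 0.09 and -0.01 ± 0.10. Without 1 library the values ranged from -0.088 to -0.023 for Rpl3, -0.061 to -0.012 for Rpl4, -0.091 to -0.0081 for Atp5a1 and -0.21 to -0.072 for Psmd2, and those of Atp5b and Psmd1 turned in sign. Adjusted over each list alone 0 genes passed in edgeR, with 2 in each list at an unadjusted p under 0.05. Camera gave adjusted p of 0.00705, 0.0184 and 0.0303 with the preset correlation and 0.749 for each with an estimated one, and 0.144 for the proteasome with the replicate block. Without WT replicate 1 the 3 adjusted p were 0.423, 0.818 and 0.214, with the ribosomal list turned in direction. Without cKO replicate 2 they were 0.283, 0.124 and 0.283, and the proteasome call was also lost without WT replicate 3 (0.217) or cKO replicate 4 (0.159), and with no filter (0.103).

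In all, 10 of the 34 lists tested passed camera with the preset correlation, 6 with higher and 4 with lower values in cKO. With an estimated correlation 0 of the 34 passed, with 0 at an unadjusted p under 0.05, and fry's test of one direction passed 0, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.46. The other 24 lists had adjusted p between 0.0544 and 0.994 with the preset correlation. Among them were markers of microglia (0.354), astrocytes (0.318), inhibitory neurons (0.459), choroid plexus (0.0931) and ependymal cells (0.0544). The choroid plexus mean was 1.38 in cKO replicate 4 and -0.53 to -0.07 in the other 6 libraries, over 5 measured genes. Without cKO replicate 4 fewer than 5 of its genes passed the filter, so that list was not tested there. Leaving out 1 library brought 10 of the 24 past the threshold in at least 1 case. The adjusted p of astrocyte markers was 0.0304 without WT replicate 2, and that of choroid plexus markers 0.0165, 0.0378 and 0.0222 without WT replicate 1, WT replicate 2 and cKO replicate 1, 0.0344 with DESeq2, 0.00788 with no filter and 0.00772 on log2(FPKM + 1) with no filter. That of ependymal markers was 0.0115 without WT replicate 3 and 0.00362 without cKO replicate 3, 0.0231 without cKO replicates 3 and 4, 0.0327 with DESeq2, 0.0197 with the stricter filter, 0.046 with lists without shared genes, and 0.0324 to 0.0484 with the other scalings. Single members of these 24 lists passed adjusted over the list alone: Aqp4, the astrocyte water channel (0.29 ± 0.08, SE), Slc17a6, the glutamate transporter of subcortical neurons (0.43 ± 0.13), and Mdm2, the ubiquitin ligase of p53 (0.30 ± 0.08), each higher in cKO. With the replicate block Slc17a6 kept this call and Aqp4 and Mdm2 lost it.

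**Figure D3:**
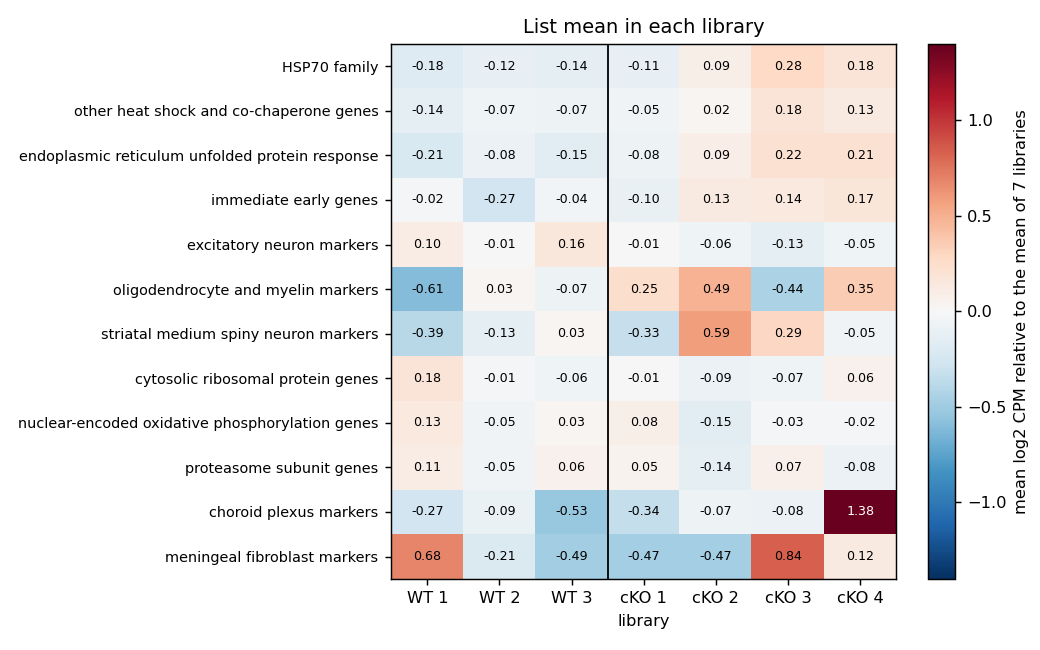
Mean log2 CPM of each list (rows) in each library (columns), relative to the mean of the 7 libraries, for the 10 lists that passed camera with the preset correlation and for markers of choroid plexus and meningeal fibroblasts; the line parts WT from cKO. The HSP70 family mean is -0.11 in cKO replicate 1 and 0.09 to 0.28 in the other cKO libraries, against -0.18 to -0.12 in WT.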

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

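Gaps between 1 cKO library and the other 3, wide enough relative to the range of all 4 to pass Dixon's test, were found in 12 of 125 sets of values (9.6%), where chance gives about 1 in 20. Several of the genes were looked at because 1 library stood out, so this share is not an estimate over all genes. The test of olfactory bulb genes below used genes not looked at before, and its bound was set in advance; the other gene choices of this part were made after the values were seen.

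In cKO replicate 3, Cdhr1 had 102.7 CPM against 1.06 to 2.53 in the other cKO libraries, Ndst4 58.4 against 1.75 to 3.46, Calb2 55.7 against 5.45 to 7.58, Sp8 22.9 against 2.19 to 2.65, Th 19.8 against 1.19 to 2.39, and Doc2g 11.3 against 0.752 to 1.15. The same library had 3.38 CPM of Atf3 against 0.723 to 1.07, the lowest Tia1 of its group (72.7 CPM against 80.3 to 81.9) and the highest mean of inhibitory neuron markers (0.18 against -0.05 to -0.01). In cKO replicate 4, Ttr, the main transcript of the choroid plexus, had 153.6 CPM against 7.10 to 12.8, and the mean of choroid plexus markers was 1.38 against -0.34 to -0.07. Among the cKO libraries the immediate early gene mean was lowest in replicate 1 (-0.10 against 0.13 to 0.17).

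Cdhr1, Doc2g, Th, Calb2 and Sp8 are known from mitral, tufted and periglomerular cells of the olfactory bulb, and a candidate explanation is that some of that tissue was dissected with cKO replicate 3. For 9 further olfactory bulb genes, written down before their values were read, 6 passed the filter; their mean in that library was 0.81 above the next highest library on the log2 scale. This fell short of the difference of 1 set in advance, so the test did not settle the explanation, though the value also lay outside the range of the other 6 libraries (-0.18 to -0.02). Meis2, the most abundant of the 6 and also expressed in cortex, had 229 CPM against 113 to 155 elsewhere. The mean leaves out Eomes, Tbx21 and Scgn, which did not pass the filter. In cKO replicate 3 they had 216, 33 and 64 counts, against 0 to 4, 0 to 4 and 0 to 7 elsewhere. No biological explanation was tested for this pattern, and the genotype is shared with the other cKO libraries, which did not show it.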

How the results depend on the processing

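The alternatives without cKO replicates 3 and 4, with lists without shared genes and without Hspa1a and Hspa1b were chosen after the data were seen; the others were planned. The count of called genes was 0 in edgeR under RLE, upper quartile and library size scaling, the stricter filter, Y-linked expression as a covariate, protein-coding genes alone, an adjusted p under 0.1 and a fold change of at least 1.5, and 0 in limma-voom and on FPKM values with a filter. It was 198 with no filter, 3 with DESeq2, 3 on log2(FPKM + 1) with no filter, 2 with the replicate block, 1 without cKO replicates 3 and 4, and 0 to 3 without 1 library (1 without WT replicate 1, 3 without WT replicate 2, 1 without cKO replicate 4). With no filter the median total degrees of freedom of the edgeR test rose from 12.03 to 156385, so the spread of single genes no longer entered, which shows how the 198 arose; the cause of the other differences was not tested. Tia1 kept its sign under 19 of 20 alternatives, and its log2 fold change was -0.062 to 0.28 without 1 library. The HSP70 list's adjusted p kept its side under 18 of 23; it was 0.749 with an estimated correlation, 0.617 with fry, 0.237 without cKO replicates 3 and 4, 0.0772 without Hspa1a and Hspa1b, and 0.000138 to 0.0524 without 1 library. The number of lists past the threshold was 0 with an estimated correlation and 0 with fry, and 8 to 14 without 1 library.

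Of 1180 values of 59 other genes recomputed under each alternative, 1123 kept their sign and side, 28 passed the threshold (most with no filter) and 29, of 9 genes with small fold changes, turned in sign. With the replicate block Ddx3x had 0.057, Atp5b 0.0055 and Psmd1 0.029; with Y-linked expression as covariate Hspa1l had 0.021 and Ddx3x 0.011; without cKO replicates 3 and 4 Hspa13 had -0.039, Hspa8 -0.16, Hspa12a -0.014, Hspa9 -0.0046, Hspa1l 0.031 and Ddx3x 0.036. Without 1 library, Hspa13 ranged from -0.025 to 0.16, Hspa8 from -0.054 to 0.16, Hspa12a from -0.021 to 0.13, Hspa9 from -0.014 to 0.085, Hspa2 from -0.17 to 0.051, Hspa1l from -0.11 to 0.095, Ddx3x from -0.14 to 0.10, Atp5b from -0.082 to 0.012 and Psmd1 from -0.094 to 0.042. With the block, Hspa4l, Hsph1, C1qa, Stx1a, Cck, Gad1, Drd2, Rxrg and Rpl30 also passed adjusted over their lists alone, and Fxr1, Manf, Mdm2, Aqp4, Ermn and Aspa no longer did. Depth was alike in all libraries and limits only genes with few counts, such as Hspa1l at 2.37 CPM in WT.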

Other observations

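The tests of this part on Tia1 and HSP70, the count of splits for the HSP70 mean, and the settings without cKO replicates 3 and 4 and with lists without shared genes, were chosen after the results were seen; the counts of splits for genes and lists were not, and the count with no filter was added once its 198 genes were known. Of the lists not yet described, the p53 and apoptosis genes did not shift to one side (adjusted p = 0.312, 13 positive and 6 negative values of 19), but fry's test of change in either direction gave an adjusted p of 0.0138, the only list of 34 it passed. Genes linked to amyotrophic lateral sclerosis (adjusted p = 0.736, 12 positive and 18 negative), autophagy and lysosome genes (0.387), neurofilament and axon cytoskeleton genes (0.944) and disease-associated microglia genes (0.155) did not pass camera with the preset correlation in all 7 libraries, nor without any 1 of them, though the last had 0.05003 without cKO replicate 2. The lists that follow did not pass in all 7 libraries but did in some other settings. Synapse genes had 22 negative values of 30 (adjusted p = 0.0688); the adjusted p was 0.0028 without WT replicate 2, 0.0129 without cKO replicate 3, 0.0138 with DESeq2, 0.0436 with upper quartile scaling, 0.0458 on log2(FPKM + 1), 0.013 there with no filter, and 0.0245 with lists without shared genes. Markers of corticospinal and other layer 5 output neurons (0.0772, median -0.13) had 0.00793 without WT replicate 2, 0.0129 without cKO replicate 2, 0.0381 without cKO replicate 3, 0.0383 with DESeq2 and 0.0165 with lists without shared genes. Interferon-stimulated genes had 17 positive values of 25 (0.104), with 0.000626 without WT replicate 1, 4.58e-05 without cKO replicate 2, 0.027 with no filter and 0.048 on log2(FPKM + 1) with no filter, and turned in direction without cKO replicates 3 and 4 (0.499). Inflammatory cytokine and complement genes had 9 negative values of 13 (0.125), with 0.0468 without WT replicate 2, and reactive astrocyte genes (0.318) had 0.0392 without WT replicate 1. Meningeal fibroblast markers (0.944) had 0.00431, higher in cKO, without WT replicate 1 and 0.00494, lower in cKO, without cKO replicates 3 and 4, and blood cell markers (0.502) had 0.0147 without WT replicate 3.

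In some genes 1 library stood apart from the rest of its group. These genes were chosen after their values were seen. Cadm2, a synaptic adhesion gene, had 446, 466 and 591 CPM in cKO replicates 1 to 3, but 235 in cKO replicate 4, within the WT range of 222 to 271. Cntnap5a had 0 CPM in cKO replicate 2 and 30.8 to 82.8 in the other 6 libraries. Within 2 Mb on each side of Tia1, 4 of 61 tested genes (6.56%) had an unadjusted p under 0.05, against 7.14% of all genes; all 4 were lower in cKO. They included Snrpg, which lies beside Tia1 on chromosome 6 (7.00 ± 1.04 CPM in WT, n = 3, and 5.16 ± 0.645 in cKO, n = 4), and Emx1, a gene of cortical excitatory neurons (14.0 ± 1.24 and 10.8 ± 1.70 CPM); neither passed in edgeR after adjustment (adjusted p = 0.694 for both).

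The real split of the libraries into 3 and 4 called 0 genes in edgeR, with 1164 at an unadjusted p under 0.05 (3 called by DESeq2, 0 by limma-voom). All 35 of 35 splits must reach a count of 0, so for the gene count this comparison says nothing about chance; the highest other count was 125. That split set WT replicates 1 and 3 with cKO replicate 3 against the rest, groups that genotype does not part. It was singled out for its count, and what lies behind its calls was not tested. These 3 libraries have the fewest genes with a count and the lowest myelin means (-0.61, -0.07 and -0.44). With no filter, 11 of 35 splits called at least the 198 genes of the real split, and the highest other count was 864. As many lists as the real 10 passed in 15 of 35 splits, with up to 15 in another split. The HSP70 mean differed by 0.26 in the real split and at least as far in 2 of 35, the other being cKO replicates 2 to 4 against the rest, at 0.32. That the libraries fell into these groups by chance can thus not be excluded for the count with no filter, the number of lists or the HSP70 mean. Among the 8 splits that part all 3 same-numbered pairs, no other had an HSP70 mean difference as large (at most 0.21), while 5 of the 8 gave at least 10 lists. By chance the real split would rank first in 1 of 8 cases, so this rank cannot exclude chance. These splits also rest on a weakly supported pairing and leave out the split at 0.32.

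The higher HSP70 values in cKO may come from the genotype, which this design does not separate from differences between single dissections, and were weighed against other sources. Without cKO replicate 3, for which olfactory bulb tissue was not settled above, the Hspa1b log2 fold change was 1.44 with a lower 95% bound of 0.94, which argues against that library as the whole source for this gene alone. For the family it stays open: the list's adjusted p was 0.0524 and its mean difference 0.20 ± 0.09 (SE) against 0.26 ± 0.09 with all libraries, Hspa1a had 0.62 instead of 0.99, and Hspa13, Hspa8, Hspa12a and Hspa9 turned negative. With Y-linked expression as covariate Hspa1b had 1.49 with a lower bound of 0.98, which argues against the sex of the animals for this gene. Arousal or handling before death stays open: the immediate early gene and HSP70 means correlated within groups at r = 0.56 over 7 libraries (one-sided permutation p = 0.208; Spearman's rho 0.21, p = 0.306), and r was -0.15 over 5 libraries without the 2 farthest on the immediate early gene mean.

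Tia1 counts that are not lower in the libraries labelled cKO may have several sources. Loss of the whole transcript in most cells would need a log2 fold change near -1 or below, and the lower 95% bound was -0.21, which argues against it; loss of some exons, of few cells or of the protein alone stays open, as does a label that does not match its mouse. A candidate explanation for the low Tia1 of WT replicates 1 and 3 is a genetic background these mice share: both lay outside the other 5 libraries on 1 side, by over 0.5 on the log2 scale, in 7 genes, among them Ide (59.2 and 61.6 CPM against 91.3 to 109.0), Xaf1 (3.31 and 3.90 against 11.3 to 21.8) and Sarm1 (39.0 and 35.6 against 20.5 to 24.1). By the bound set for the test this would count against it, since 2 of the 20 other pairs had as many such genes. A flaw of that bound was seen only with the result in hand. Both pairs include cKO replicate 3 and stand apart by genes of other tissues, such as Col1a1 and Dcn or Drd2 and Penk. The test therefore leaves the question open and lends a shared background no support. A structure of the libraries other than genotype stays open too. The next lowest Tia1 was in cKO replicate 3 (72.7 CPM), against 80.3 to 95.8 CPM in the remaining libraries. Setting WT replicates 1 and 3 with cKO replicate 3 against the rest was the split that called 125 genes. Its Tia1 log2 fold change, 0.33 higher in the rest, was the largest of any split. These 3 libraries have the lowest Tia1, so that rank was fixed and does not link Tia1 to the 125 genes.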
